A study of Arabidopsis thaliana with 16 samples.

How the data were processed

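The series holds 16 RNA libraries from whole Arabidopsis thaliana seedlings grown on agar plates. Per the labels, seedlings were exposed to gaseous ethanol (EtOH) for 1 d from an age of 13 d, or for 3 d from an age of 11 d. The control groups carry the label moc, which the labels do not spell out. The 4 groups are moc_1d, EtOH_1d, moc_3d and EtOH_3d, with 4 replicates each per the labels. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates were separate plates, so p-values measure the spread between these samples, which may be technical.

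Libraries were prepared from total RNA by Lasy-Seq, per the labels' protocols. Lasy-Seq is a 3' RNA sequencing method that barcodes each sample early and pools samples, so most reads fall near the 3' end of transcripts. The submitters' processing notes name bcl2fastq, Trimmomatic, HISAT2, featureCounts and DESeq2, and the genome build TAIR10, without versions. The strand setting of the read counting is not given in the sources used here. The authors deposited a table of whole-number read counts for 27416 genes, which carries no normalization. The second deposited table holds a signal that equals the count divided by 1 size factor per library. Recomputed size factors reproduced 100% of its values within a tolerance of 0.011, so that table was not used for tests.

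Before averaging, all 120 pairs of columns were compared. The columns moc_1d replicate 1 and moc_3d replicate 3 were identical for all 27416 genes in both tables. The mean chi-square per gene of pairs of a group that hold neither of these columns lay between 2.71 and 5.68, where counting noise alone gives about 1. The 2 columns are therefore 1 library under 2 labels in different groups. Which label is right is not given in the sources used here, and values were not used to decide it. The design fixed before the data were examined had 16 columns. The comparisons here leave out both columns and use 14 libraries, 3 per control group and 4 per ethanol group. The count from the 16 columns as designed is printed in the report for the number of genes called in each of the 4 comparisons. Fits that keep the library once under either label were added after seeing the data.

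Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 18419 genes. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to the 4 groups together. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in each comparison, with a threshold of 0.05. The 4 comparisons were EtOH_1d minus moc_1d, EtOH_3d minus moc_3d, the difference between these responses, and moc_3d minus moc_1d. Standard errors (SE) of log2 fold changes were derived from the test statistic. CPM are counts scaled to the same TMM-adjusted total in each library.

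In total 25 gene lists with 442 memberships were fixed as locus codes before the data were examined, and all members have a row in the tables. The lists cover cold transcription factors (cold_TF), cold-regulated genes downstream of CBF (COR), ABA, ethanol and acetate metabolism, hypoxia, heat shock, the unfolded protein response (UPR), redox, flavonoids, starch, osmolytes, sugar starvation, photosynthesis, root markers, salicylic acid (SA) defence, jasmonate (JA), ethylene and touch, clock, senescence, auxin and growth, glucosinolates, membrane lipids, wax, iron and phosphate. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run on the same lists. Lists needed at least 5 tested members.

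The rule for named genes was fixed in advance. In each comparison it takes the 5 largest rises and the 5 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries of the 2 groups (this last condition not for the difference of responses). In the ethanol comparisons it adds up to 3 members with the smallest p from each called list. ADH1, CBF1, CBF2, CBF3, COR15A, COR15B, COR47, RD29A, KIN1, KIN2, GOLS3, RD29B and RAB18 are always named. Other genes named were chosen after their values were seen, and the text says so.

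Gene symbols and coordinates come from the TAIR10.1 annotation, where 26719 of the 27416 locus codes have an entry. The last 500 nt of 639 transcripts were searched with BLAST 2.17.0 for other loci sharing at least 100 nt at 95% identity. Of the genes called at 3 d, 1 had such a locus and 24 overlap another counted gene. Among all tested genes, 107 carry counts equal to those of another tested gene in every library. Such genes share reads, or may do so, and their values are uncertain to that extent.

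Total counts ranged from 3695511 to 15943927 in the 14 libraries, so 3 counts correspond to 0.188 to 0.812 CPM. The biological coefficient of variation was 9.11%. The scripts were tested on simulated data for 18419 genes with the real means, dispersions and library sizes. In the comparison at 1 d, 16% of genes changed 1.25-fold were recovered, 46% of those changed 1.5-fold, 86% at 2-fold and 94% at 3-fold, with 10 unchanged genes called. In the comparison at 3 d, the shares were 6%, 48%, 74% and 86%, with 2 unchanged genes called. A simulated list of genes raised 1.25-fold was called by camera with either correlation and by fry in both comparisons, and 0 of 24 unshifted lists were. Simulated genes varied independently of each other, while the estimated correlation in the real lists reached 0.476, for hypoxia. The simulation therefore cannot show how often a real list is called falsely.

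Alternatives were DESeq2 size factors, no low-count filter, a stricter filter, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block, thinning to the smallest library, leaving out organelle genes, a minimum log2 fold change of 1, fits of only the groups compared, and leaving out each library. Figures were drawn with matplotlib 3.10.9.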

Results

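Whole seedlings of Arabidopsis thaliana on agar plates were kept with ethanol vapour over 1 d or 3 d and compared with control seedlings, labelled moc, of each duration. The series title names freezing stress. No label gives a cold or freezing step for these samples, so the libraries are read here as seedlings after ethanol without such a step. Total counts were 6056980 to 11458250 in moc_1d, 5659976 to 15943927 in EtOH_1d, 5407735 to 7696919 in moc_3d and 3695511 to 6340751 in EtOH_3d. Nothing in the labels says that replicates come from separate plates, so p-values measure only the spread between these samples. Between 21122 and 22892 genes had at least 1 count. RBCS1A (AT1G67090), a small subunit of Rubisco, took the most counts in each library, at 2.14% to 2.53%.

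The columns moc_1d replicate 1 and moc_3d replicate 3 held identical counts, with a total of 6209714 in each. This library was left out of both groups, and comparisons rest on 3 control and 4 ethanol libraries per duration. In a principal component analysis, the first component (15.2% of the variance) separated the 7 libraries of 1 d from the 7 of 3 d. The control library moc_3d replicate 1 stood apart on the second component (12.5%), at 17.8 against 4.65 and 5.01 for the other 3 d controls. The share of chloroplast counts was 1.302% ± 0.21 (SD, n = 3) in moc_3d and 1.71% ± 0.18 (SD, n = 4) in EtOH_3d, against 1.72% ± 0.12 (n = 3) in moc_1d and 1.97% ± 0.31 (n = 4) in EtOH_1d.

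The first comparison asked which transcripts differed after 1 d of ethanol. Genes of the darkness and sugar starvation list lay slightly above their controls, with a mean log2 fold change of 0.19 and 19 of 20 members positive. TPS8 (AT1G70290), a class II trehalose phosphate synthase-like protein, had a log2 fold change of 0.38 ± 0.08 (SE), from 36.9 to 48.2 CPM. SEN5 (AT3G15450), a gene induced in darkness, had 0.26 ± 0.06, from 684 to 817 CPM, and BT2 (AT3G48360), a BTB/TAZ protein repressed by sugar, had 0.26 ± 0.07. None of the 3 passed over all genes (adjusted p = 0.0908, 0.0908 and 0.651). With p adjusted over the list alone, 4 members passed, the 3 genes above and TPS11 (0.33). The COR list, cold-regulated genes downstream of the CBF factors, had a mean of 0.20 with 15 of 17 members positive, and 3 members passed when adjusted over the list alone. These were the dehydrins XERO2 (0.27 ± 0.08) and COR47 (0.18 ± 0.06) and the clock-linked COR28 (0.60 ± 0.20).

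Both lists were called by camera with the preset correlation (adjusted p = 7.08e-06 for sugar starvation and 0.000336 for COR). Neither call held with an estimated correlation (adjusted p = 0.307 and 0.597) or by fry (0.152 and 0.594). The other 23 lists were not called. Their means ran from -0.27 for iron, with the smallest adjusted p among them (0.0548), to 0.20 for osmolytes. Over all genes, 0 of 18419 passed the edgeR test at 1 d, where the smallest adjusted p was 0.0908. At an unadjusted p under 0.05 there were 795 genes, with 921 expected by chance. DESeq2 called 0 genes, limma-voom 1 and edgeR on the 16 columns as designed 2, while the fit of only the 2 groups compared called 16, all higher with ethanol. Without the low-count filter the count was 28. Without moc_1d replicate 3 it was 5 and without EtOH_1d replicate 1 it was 3.

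The second comparison asked the same after 3 d. The clearest change was a rise of genes known to be induced by darkness and sugar starvation. SEN5 (chromosome 3, 5212984 to 5214124 in TAIR10.1) rose from 848 ± 51 (SD, n = 3) to 1167 ± 45 CPM (SD, n = 4), a log2 fold change of 0.46 ± 0.06 (SE) with adjusted p = 5.98e-07. DIN10 (AT5G20250; chromosome 5, 6833564 to 6836862), a raffinose synthase family gene, rose from 169 ± 21 to 260 ± 22 CPM (0.62 ± 0.08, adjusted p = 2.39e-06). BT2 (chromosome 3, 17907767 to 17910738) rose from 172 ± 15 to 258 ± 24 CPM (0.58 ± 0.08, adjusted p = 3.35e-06). DIN1 (AT4G35770), the senescence-associated SEN1, rose from 106 to 201 CPM (0.93 ± 0.14). DIN1 passed over all genes (adjusted p = 0.0102) but not without moc_3d replicate 1 (0.0774) or moc_3d replicate 4 (0.054), while SEN5, DIN10 and BT2 passed whichever library was left out. In the 16 columns as designed BT2 missed the threshold (adjusted p = 0.133). In each of these 4 genes every ethanol library lay above every control library of 3 d. SEN5 and DIN10 overlap a gene on the opposite strand, whose reads would be mixed with theirs if the counting ignored strand.

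Of the 20 members of this list, all tested, 16 had positive and 4 negative log2 fold changes, with a mean of 0.32. Over all genes, 7 members passed, all higher. Besides the 4 above these were BXL1 (0.64 ± 0.09), a cell wall xylosidase, MCCA (0.62 ± 0.14), a subunit of the leucine-degrading enzyme methylcrotonyl-CoA carboxylase, and TPS8 (0.38 ± 0.08); these 3 and the list members named next were chosen after their values were seen. Adjusted over the list alone, 14 passed, among them ASN1 (0.70 ± 0.18), the dark-induced asparagine synthetase, and GDH2 (0.32 ± 0.08), a glutamate dehydrogenase. DIN9 had the most negative value (-0.67 ± 0.36), at 3.97 CPM in controls and 2.38 with ethanol. The list was called by camera with the preset correlation (adjusted p = 9.41e-14), with an estimated correlation (adjusted p = 0.022) and by fry (adjusted p = 0.000464). The call with an estimated correlation ended without moc_3d replicate 4 (adjusted p = 0.0577), EtOH_3d replicate 2 (0.0592) or EtOH_3d replicate 4 (0.0623), while fry kept it without each of the 7 libraries.

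**Figure D1:**
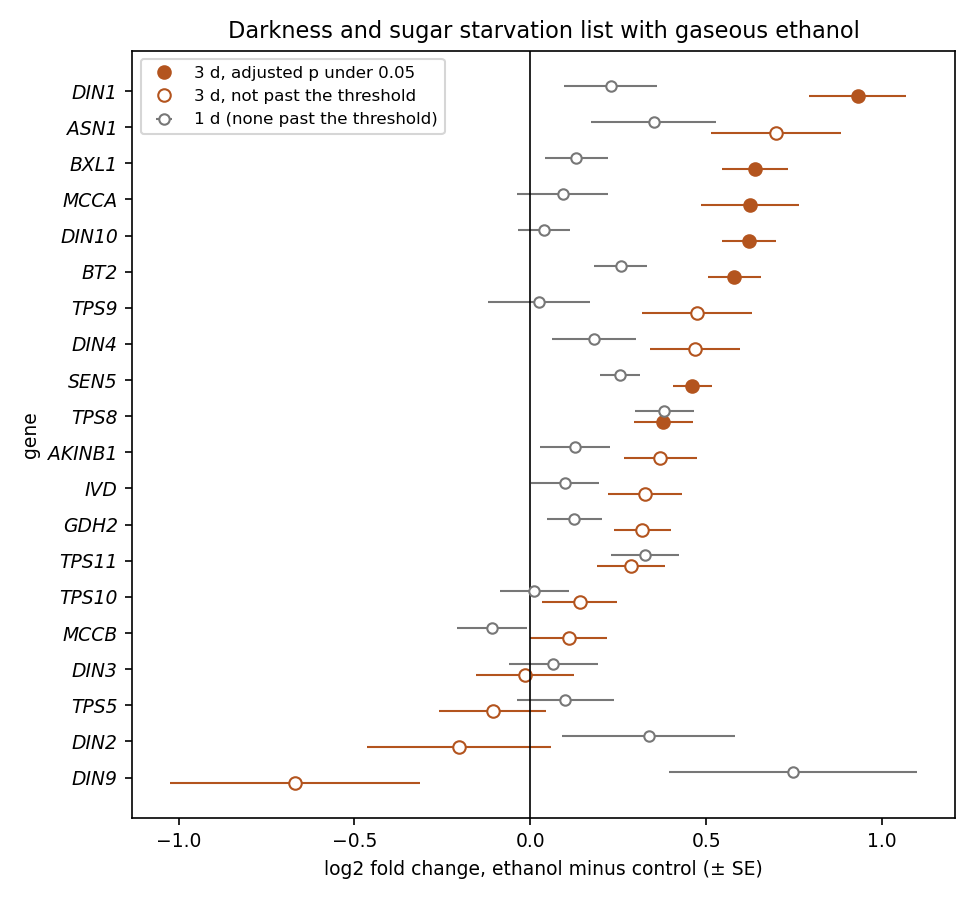
Log2 fold change of ethanol minus control for the 20 genes of the darkness and sugar starvation list (bars: SE) at 1 d (grey) and 3 d (orange; filled where adjusted p was under 0.05). At 3 d 16 genes lie right of 0 and 7 are filled; at 1 d 19 lie right of 0 and none passed the threshold.

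In all, 102 of 18419 genes differed at 3 d, 81 higher and 21 lower with ethanol, with a median absolute log2 fold change of 0.40. Only 3 of them changed by at least 1 on the log2 scale. By the rule for named genes, the other large rises were AT2G05540, a glycine-rich protein (0.95 ± 0.11, from 78.4 to 152 CPM), AT1G24530, a WD40 repeat protein (0.89 ± 0.20), AT1G23880, an NHL domain protein (0.82 ± 0.18), and AT5G19950, a tudor domain protein (0.73 ± 0.17). The large falls were UMAMIT14 (AT2G39510; -1.24 ± 0.28, from 14.8 to 6.04 CPM), an amino acid exporter, and LSU1 (AT3G49580; -0.89 ± 0.19, from 20.3 to 11.0 CPM), a marker of sulfur limitation. AT3G15350 (-0.74 ± 0.19), a glycosyltransferase family gene, CORI3 (AT4G23600, -0.71 ± 0.17), a jasmonate-responsive cystine lyase, and AT3G44450 (-0.63 ± 0.14) also fell. Without moc_3d replicate 1 all of these but AT2G05540 missed the threshold: AT1G24530 (adjusted p = 0.163), AT1G23880 (0.114), AT5G19950 (0.171), UMAMIT14 (0.149), LSU1 (0.226), AT3G15350 (0.406), CORI3 (0.256) and AT3G44450 (0.0792). All but AT1G23880 also missed it without at least 1 other library. Without moc_3d replicate 1 the value of CORI3 was -0.467, that of LSU1 -0.622 and that of UMAMIT14 -0.947.

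Other genes called at 3 d were chosen after their values were seen and not tested as a group: the hexose transporter STP1 rose by 0.54 ± 0.07 and the galactosidase BGAL4 by 0.72 ± 0.11. The transcription factor bZIP1 rose by 0.42 ± 0.09, and the locus AT5G49448, also called, carries counts equal to those of bZIP1 in every library.

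The 16 columns as designed gave 66 genes at 3 d, 60 of them shared with the 102. Without moc_3d replicate 1 the count was 43, of which 39 were shared.

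**Figure D2:**
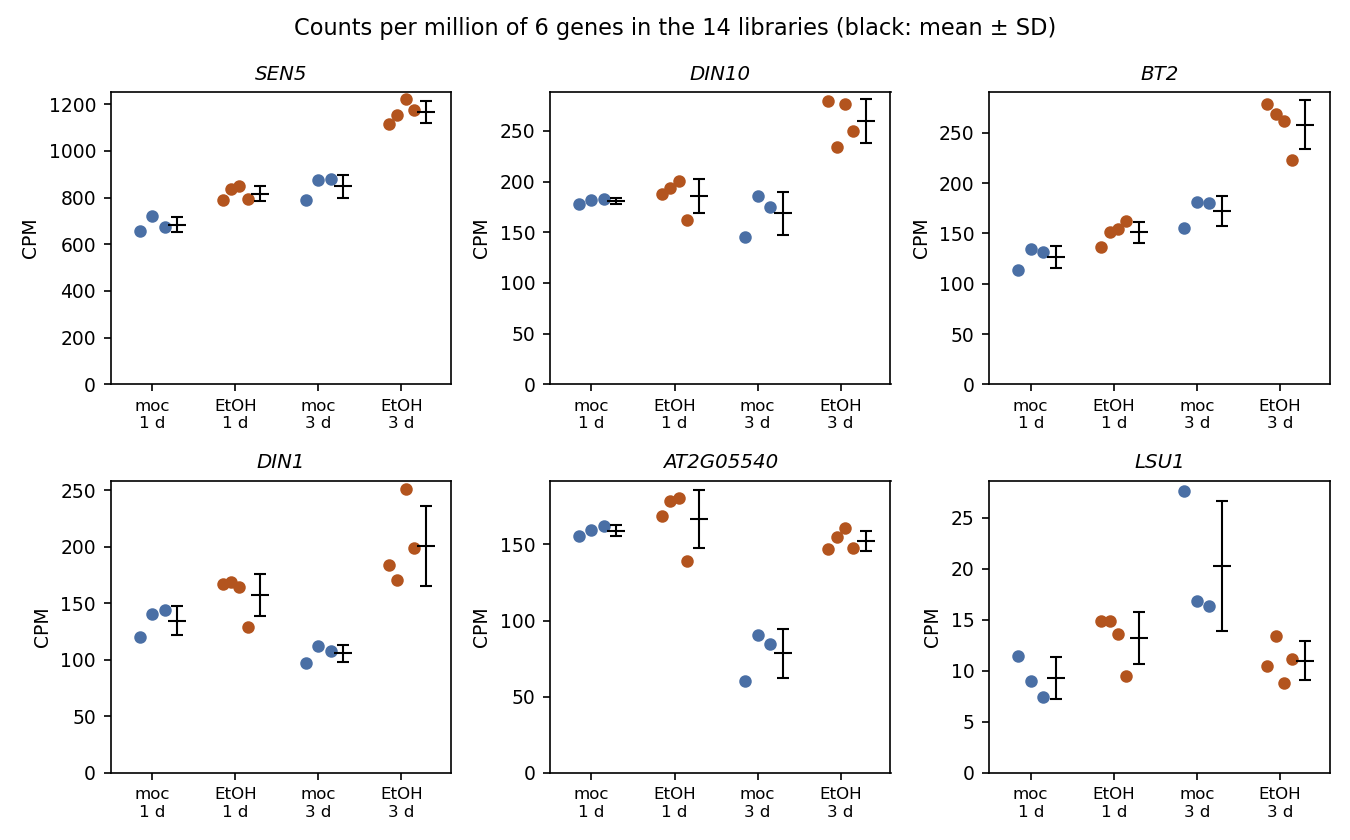
CPM of 6 genes in each of the 14 libraries, by group (blue: control, labelled moc, n = 3; orange: ethanol, n = 4), with mean and SD in black. SEN5, DIN10, BT2, DIN1 and AT2G05540 are higher and LSU1 lower in EtOH_3d than in moc_3d, and the 3 d controls of AT2G05540 lie below those of 1 d.

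Another 4 lists were called lower at 3 d by camera with the preset correlation, and none held with an estimated correlation. The iron list had a mean of -0.59 with 12 of 15 members negative (adjusted p = 0.00184, and 0.544 with an estimated correlation). Its members with the smallest p were NAS4 (-0.55 ± 0.21), a nicotianamine synthase, BHLH39 (-1.58 ± 0.51), an iron deficiency transcription factor, and IMA3 (-0.80 ± 0.35), an iron-responsive peptide, none of which passed over all genes. The flavonoid list had a mean of -0.23 with 13 of 16 negative (adjusted p = 0.00369, and 0.373 with an estimated correlation). F3H had -0.48 ± 0.14, the transport-linked GSTF12 -1.02 ± 0.34 and FLS1 -0.34 ± 0.14, of which F3H and GSTF12 passed when adjusted over the list alone. The glucosinolate list had a mean of -0.10 with 14 of 21 negative (adjusted p = 0.0121, and 0.373 with an estimated correlation). CYP79F1 had -0.27 ± 0.07, the regulator MYB28 -0.35 ± 0.10 and FMOGS-OX1 -0.36 ± 0.15, of which CYP79F1 and MYB28 passed over the list alone. The hypoxia list had a mean of -0.22 with 18 of 21 negative (adjusted p = 0.0289, and 0.963 with an estimated correlation). Its 3 members with the smallest p went both ways, HUP32 (0.51 ± 0.17) and HUP6 (0.47 ± 0.29) up and WIP5 (-0.95 ± 0.47) down, and none passed. HUP32 overlaps AT1G33050 on the same strand and shares 123 nt with it at 100% identity, so their reads may be mixed. Without moc_3d replicate 1 all 4 of these calls ended, with means of -0.21 for iron, -0.17 for flavonoids, -0.08 for glucosinolates and -0.06 for hypoxia (adjusted p = 0.179, 0.0528, 0.126 and 0.764). The hypoxia call also ended without moc_3d replicate 4 (0.105) or EtOH_3d replicate 1 (0.129), 2 (0.316) or 3 (0.117).

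The other 20 lists were not called at 3 d. Mean log2 fold changes were -0.25 for cold_TF, -0.24 for SA defence, -0.12 for osmolytes, -0.12 for root markers, -0.11 for starch, -0.10 for JA, -0.10 for ethylene and touch, -0.07 for UPR and -0.07 for senescence. They were -0.06 for COR, -0.02 for ABA, -0.01 for membrane lipids, 0.03 for ethanol and acetate metabolism, 0.03 for auxin and growth, 0.02 for phosphate, 0.08 for the clock and 0.10 for wax. In COR 5 members were positive and 12 negative, and 2 passed when adjusted over the list alone, both higher with ethanol. Photosynthesis (-0.001), heat shock (-0.004) and redox (0.003) lay nearest to 0.

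Genes named in advance for the series title and the compound gave no call at either duration. ADH1 (AT1G77120), alcohol dehydrogenase, had 44.7 ± 5.4 CPM (SD, n = 3) in moc_1d and 39.5 ± 9.2 (n = 4) in EtOH_1d, and 54.9 ± 19.6 (n = 3) and 39.3 ± 21.7 (n = 4) at 3 d. Its log2 fold changes were -0.19 ± 0.36 (95% interval -0.89 to 0.52) and -0.44 ± 0.38 (-1.18 to 0.30). At 1 d COR15A had 0.43 ± 0.28, COR15B 0.54 ± 0.19, RD29A 0.24 ± 0.12, KIN1 0.37 ± 0.24, KIN2 0.42 ± 0.16 and RAB18 0.59 ± 0.27. At 3 d they had -0.45 ± 0.28, -0.10 ± 0.20, -0.22 ± 0.13, -0.30 ± 0.23, -0.01 ± 0.16 and -0.03 ± 0.31. COR47 had 0.19 ± 0.06 at 3 d. CBF1, CBF2, CBF3 and GOLS3 stayed below 5 CPM in every group mean, with 3 d values of -0.21 ± 0.58, -1.12 ± 0.42, -0.72 ± 0.36 and -0.63 ± 0.36. At 1 d these 4 had 0.29 ± 0.60, -0.31 ± 0.34, 0.26 ± 0.29 and 0.07 ± 0.33. RD29B was not tested because of low counts.

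**Figure D3:**
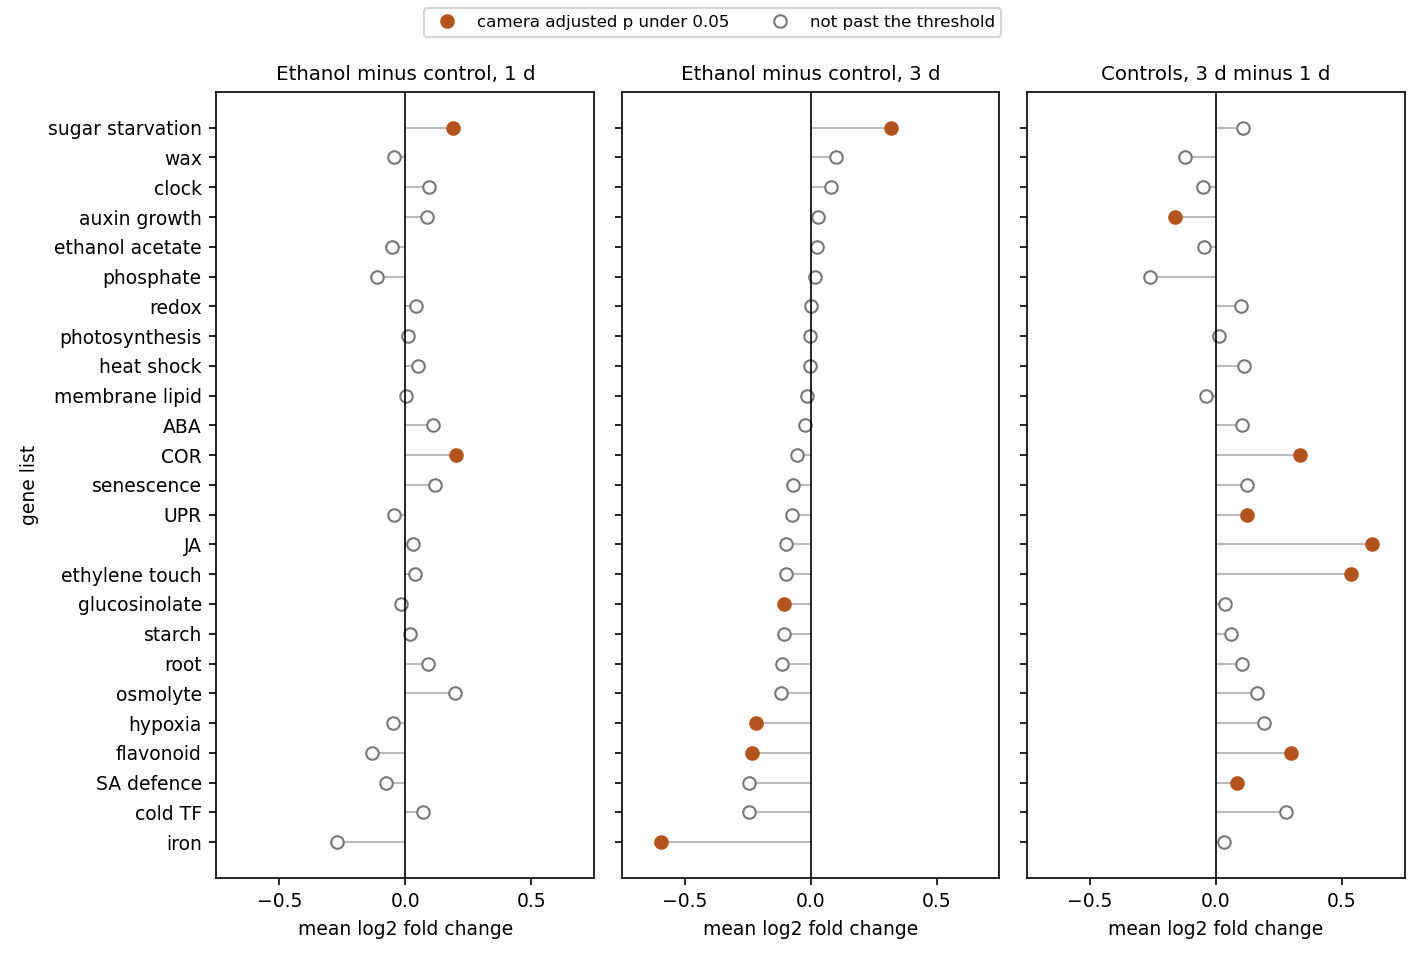
Mean log2 fold change of the tested members of each of the 25 gene lists in 3 comparisons (filled: camera adjusted p under 0.05 with the preset correlation). Sugar starvation is the only list filled at 1 d and 3 d in the same direction, and JA and ethylene and touch have the largest means between the controls.

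The third comparison tested whether the response at 3 d differed from that at 1 d. For 8 genes it did, 5 with a more positive and 3 with a more negative response at 3 d. DIN10 changed by 0.04 ± 0.08 at 1 d and 0.62 ± 0.08 at 3 d, a difference of 0.58 ± 0.11 (adjusted p = 0.0129). AT1G22890, of unknown function, had the smallest adjusted p (0.00441) with a difference of 0.79 ± 0.14. AT2G05540 (0.88 ± 0.15), the monooxygenase MO1 (0.58 ± 0.12) and the chloroplast gene ATCG00740 (0.47 ± 0.09), which encodes an RNA polymerase subunit, were the others with a more positive response. LSU1 (-1.36 ± 0.27) and RFNR2 (-0.66 ± 0.13), a root ferredoxin-NADP reductase, had a more negative one. GOLS2 (-2.04 ± 0.40), a galactinol synthase below the minimum of 5 CPM for named genes, completes the 8. It stood at 2.89 CPM in moc_1d, 5.65 in EtOH_1d, 6.23 in moc_3d and 2.79 in EtOH_3d. In the same order AT2G05540 had 159, 167, 78.4 and 152 CPM, and ATCG00740 862, 803, 678 and 878. LSU1 had 9.27, 13.2, 20.3 and 11.0 CPM, and RFNR2 68.9, 80.3, 123.9 and 91.6. In AT2G05540, ATCG00740, LSU1 and RFNR2 moc_3d stood furthest from the other groups, so their difference rests on the 3 d controls. In DIN10 (181, 186, 169 and 260 CPM) and MO1 (51.4, 49.7, 48.1 and 69.2) EtOH_3d did. In AT1G22890 (48.05, 42.18, 34.31 and 52.63 CPM) moc_3d was lowest and EtOH_3d highest. In GOLS2 moc_3d lay near EtOH_1d, and EtOH_3d near moc_1d.

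In the 14 libraries 1025 genes had an unadjusted p under 0.05 by edgeR, with 921 expected by chance. The 16 columns as designed gave 0 genes past the adjusted threshold, and in the 14 libraries DESeq2 gave 16 and limma-voom 2. Leaving out a library gave 1 gene without moc_1d replicate 4 or EtOH_3d replicate 3, 2 without moc_3d replicate 1, 4 without EtOH_3d replicate 1, 5 without EtOH_1d replicate 1, 15 without EtOH_3d replicate 4 and 23 without moc_3d replicate 2. AT1G22890 alone kept its call in each of these fits. DIN10 missed the threshold without moc_1d replicate 4 (adjusted p = 0.0516), moc_3d replicate 1 (0.101) or EtOH_3d replicate 3 (0.0529). By camera with the preset correlation, the sugar starvation list had the more positive response at 3 d (mean difference 0.13, adjusted p = 0.000944) and COR the more negative (-0.26, adjusted p = 0.00816). Both calls were lost with an estimated correlation (adjusted p = 0.861 and 0.871). The COR call was also lost without moc_1d replicate 2, EtOH_1d replicate 3, moc_3d replicate 1 or EtOH_3d replicate 1 (adjusted p = 0.144, 0.112, 0.264 and 0.12). Its mean differences in these fits were -0.208, -0.211, -0.166 and -0.196, in this order.

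No gene was shared between the 2 durations, since none was called at 1 d. Across all genes, which are not independent replicates, the log2 fold changes of 1 d and 3 d had a Pearson correlation of 0.05 and a Spearman correlation of 0.06. Different control libraries entered the 2 comparisons. Of the 81 genes raised at 3 d, 65 had a positive log2 fold change at 1 d, with a median of 0.09 against 0.40 at 3 d. As a set, they lay higher at 1 d by camera (p = 1.5e-10, and p = 0.0345 with an estimated correlation) and by fry (p = 0.0145). Of the 21 genes lowered at 3 d, 10 were negative at 1 d.

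The fourth comparison gave the background between the control groups. Of 21 jasmonate genes tested, 5 were higher in the controls of 3 d than in those of 1 d. JAZ7 (AT2G34600), a repressor of jasmonate signalling, had the largest rise by the rule for named genes, from 1.26 ± 0.05 (SD, n = 3) to 7.13 ± 4.05 CPM (n = 3), a log2 difference of 2.45 ± 0.36 (SE). The JA list had a mean of 0.62 with 17 of 21 members positive, but its call did not hold with an estimated correlation (adjusted p = 0.363) or by fry (adjusted p = 0.21). Without moc_3d replicate 1 its mean was 0.22. The 5 members that passed over all genes were JAZ7, the lipoxygenase LOX4 (2.24 ± 0.45), JAZ9 (0.82 ± 0.20) and the synthesis genes AOC2 (0.49 ± 0.11) and OPR3 (0.47 ± 0.12); 6 passed when adjusted over the list alone. The ethylene and touch list had a mean of 0.54, and 0.25 without moc_3d replicate 1, with 13 of 15 positive, and the calmodulin-like TCH3 (0.93 ± 0.21) and TCH2 (0.75 ± 0.22) passed over the list alone. The COR list had a mean of 0.34 with 16 of 17 positive and 5 passing over the list alone, among them KIN1 (0.93 ± 0.25) and COR15B (0.65 ± 0.21). The list members named for the controls were chosen after their values were seen.

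Flavonoid (mean 0.30), UPR (0.12) and SA defence (0.08) lists were also called higher, and auxin and growth (-0.16) lower, where the expansin EXPA1 fell by 0.50 on the log2 scale. None of the 7 list calls between the controls held with an estimated correlation (adjusted p = 0.363 for 6 of them and 0.531 for UPR). WRKY70 (1.21 ± 0.22) was the SA defence member past the threshold. Adjusted p by camera with the preset correlation was 4.16e-08 for JA, 1.53e-05 for ethylene and touch, 5.83e-06 for COR and 0.0102 to 0.0398 for the other 4. Without moc_3d replicate 1 the JA mean was 0.22, the calls of UPR (adjusted p = 0.252), flavonoids (0.0991) and SA defence (0.238) ended, and the SA defence mean was -0.06. Without moc_1d replicate 2 the calls of UPR, SA defence and auxin and growth ended (adjusted p = 0.142 for each). Those of auxin and growth (0.0703) and flavonoids (0.182) ended without moc_1d replicate 4, and both (0.0976 for each) without moc_3d replicate 4. The UPR call ended without moc_1d replicate 3 (0.0787), and that of auxin and growth without moc_3d replicate 2 (0.0704). In the fits where its call ended, the auxin and growth mean ran from -0.196 without moc_3d replicate 2 to -0.08 without moc_1d replicate 4. The SA defence mean was 0.61 without moc_1d replicate 3. Sugar starvation (0.11) was not called, with 9 of 20 members positive. Over all genes 4 of its members passed, all higher in the 3 d controls. Among them were SEN5 (0.31 ± 0.06) and TPS8 (0.54 ± 0.09), which thus differed between groups without ethanol.

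In all, 155 genes differed between the controls, 97 higher and 58 lower at 3 d. Besides JAZ7, the rule named UMAMIT14 (1.53 ± 0.28), AT1G66090 (1.46 ± 0.27), a TIR-NBS resistance gene, AT1G02660 (1.41 ± 0.18), a hydrolase, and LSU3 (1.39 ± 0.21), a marker of sulfur limitation, as higher. It named AT3G59930 (-1.28 ± 0.30), a defensin-like gene near-identical to AT5G33355, AT2G21210 (-1.16 ± 0.16), the auxin-linked SAUR6, AT2G05540 (-1.01 ± 0.11), AT5G10770 (-0.99 ± 0.17), an aspartyl protease, and ATCG00330 (-0.93 ± 0.23), a chloroplast ribosomal protein, as lower. AT2G21210 overlaps AT2G21200 on the same strand and shares 176 nt with it at 100% identity, so their reads may be mixed. AT3G59930 missed the threshold without moc_1d replicate 2 (adjusted p = 0.174) or 4 (0.127) and without moc_3d replicate 1 (0.207) or 2 (0.174). ATCG00330 missed it without moc_1d replicate 3 (adjusted p = 0.246) or 4 (0.0681) and without moc_3d replicate 1 (0.109), 2 (0.136) or 4 (0.0586). UMAMIT14 missed it without moc_1d replicate 2 (adjusted p = 0.0687). UMAMIT14, AT2G05540 and LSU1 (1.07 ± 0.20 between the controls) moved the other way in EtOH_3d minus moc_3d, a comparison that shares the 3 d controls.

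The 16 columns as designed, which hold 1 library in both groups, gave 5 genes. Without moc_3d replicate 1 the count was 67, without moc_1d replicate 2 it was 74 and without moc_1d replicate 4 it was 85. Age at the start of treatment goes with duration, so the design does not separate them.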

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

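The tests of a single library, of the control libraries alone and of the identical columns, and the splits judged by the strongest list, were chosen after their results or the pattern were seen. The tests of harvest hour and depth and the other splits of the samples were written down before.

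Higher expression of sugar starvation genes with ethanol at 3 d (mean log2 fold change 0.32) is the first pattern weighed. A single library does not account for it: the largest p by fry over the 7 fits without a library was 8.65e-05, and the lowest mean was 0.28. With all libraries thinned to the smallest, the mean was 0.319. Thinning keeps the ratios between groups, so a mean near 0.32 would result whether or not unequal total counts contribute. Thinning therefore leaves unequal total counts open, and it cannot test differences between libraries that arose before counting. A different hour of harvest stays open, since morning minus evening clock genes differed by -0.278 (SE 0.156) between EtOH_3d and moc_3d, an interval that reaches the size of the pattern. A response to ethanol is a hypothesis that fits the groups, and a shift in harvest hour may contribute.

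The difference between the controls of 3 d and 1 d is the second. For its jasmonate part, a peculiarity of the control libraries alone is argued against by a list mean of 0.492 (SE 0.142) between EtOH_3d and EtOH_1d, which share no library with the controls, though with p = 0.0482 by fry and p = 0.084 by camera with an estimated correlation. Its COR part had a mean of 0.078 (SE 0.11) there against 0.34 in the controls, which decides nothing at this spread. The clock difference between the controls was 0.028 (SE 0.12), inside the bound set before, which was the JA mean of 0.62. This argues against a clock shift of that size. A smaller shift in the hour of harvest stays open, since the bound does not say how jasmonate genes change by hour. Whether moc_3d replicate 1 carries the pattern stays open too, since 67 genes were called without it but the JA mean fell to 0.22. Age at the start of treatment, length of treatment and handling may each contribute and were not separable. Per the labels, start age and length of treatment add up to the same age in the 1 d and 3 d groups. Age at harvest was therefore equal if seedlings were harvested when treatment ended.

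The identical columns moc_1d replicate 1 and moc_3d replicate 3 are the third. On an axis from the 1 d controls (0) to the 3 d controls (1), built from 150 genes of the other 6 controls, this library lay at 0.695. Left-out 3 d controls lay between 0.558 and 0.868 and left-out 1 d controls between 0.148 and 0.372. The position argues against a 1 d control stored also as 3 d and is consistent with a 3 d control stored also as 1 d, from 3 libraries per group. It was used for no comparison, and no biological explanation was tested.

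Other splits of the samples bear on these results. For the sugar starvation list the real split alone, 1 of 35 splits of the 7 libraries, gave a mean as large in size (highest other 0.28), but this list was picked out of 25 for its strength. Taking the strongest of the 25 lists in each split allows for that choice. Again 1 of 35 reached the real -log10 p, which was 3.06 by camera with an estimated correlation (highest other 2.77) and 4.73 by fry (highest other 3.59). This share is the smallest that 35 splits can give and was not adjusted over the 4 comparisons. It argues against chance without excluding it. For the controls, 10 splits are too few for a share under 0.05. The real split gave 155 genes and 7 lists, the highest others 3 genes and 9 lists, and 1 and 4 splits gave as many.

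For the counts, chance is argued against but not excluded for the 102 genes at 3 d. Only the real split of 35 reached that count (highest other 32), again the smallest share possible. For the 0 genes at 1 d the splits say nothing, since 35 of 35 must give at least 0 (highest other 7). Chance cannot be excluded for the 8 genes whose response differed, since 5 of 100 splits gave as many, the real one among them. Of these, 1 gave 41 genes, with a sugar starvation mean of 0.425. Labels were shuffled within each duration, so a drawn split can keep the real 3 d grouping, whose mean was 0.321. Other 3 d splits had means up to 0.214 and 1 d splits down to -0.182, whose difference falls short of 0.425. This split thus kept the real ethanol response at 3 d, so the draws measure chance for the difference only in part. For numbers of lists called by camera with the preset correlation chance cannot be excluded: 23 of 35 splits gave at least the 2 lists of 1 d (highest other 9), 15 of 35 the 5 of 3 d (highest other 8) and 77 of 100 the 2 of the difference (highest other 9).

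Responses that differed between the durations by the test of the difference itself, as log2 differences of 3 d minus 1 d, were 0.792 for AT1G22890, 0.582 for DIN10, 0.474 for ATCG00740, -2.037 for GOLS2, 0.883 for AT2G05540, -0.657 for RFNR2, -1.364 for LSU1 and 0.576 for MO1. By camera with the preset correlation the lists were COR (-0.257) and sugar starvation (0.133). Neither held with an estimated correlation (adjusted p = 0.871 and 0.861) or by fry (0.648 and 0.393).

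Of 81 sets of 4 libraries checked, 4 had a library apart from the others, and 4.0 are expected by chance at 1 in 20. FLS1 was at 21.8 CPM in EtOH_3d replicate 4 and 15.81 to 15.91 in the others (gap over range 0.983). FMOGS-OX1 was at 20.1 CPM in EtOH_3d replicate 1 against 15.91 to 16.31 (0.904). CBF1 was at 4.298 CPM in EtOH_3d replicate 2 against 0.74 to 0.95 (0.943). ATCG00740 was at 869.8 CPM in EtOH_1d replicate 1 against 776 to 783 (0.921).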

How the results depend on the processing

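The fit of 16 columns is the design fixed in advance. Leaving out both identical columns, which made it an alternative, and keeping the duplicated library once were chosen after the data were seen; the other alternatives were planned. Of the named genes and lists past the threshold with the 14 libraries, 1 changed sign under an alternative, the list of SA defence between the controls. A sign flip of a gene past the threshold in no fit was not counted as a reversal. For this list the mean was -0.07 without moc_1d replicate 2 and -0.06 without moc_3d replicate 1, where the call was lost, and -0.02 without moc_1d replicate 4, where camera still called it higher. Of the values for named genes and lists, 1319 stayed on their side of the threshold, 228 lost it and 9 gained it. The 1319 include genes that passed in neither fit and had no call to lose. These numbers therefore do not give the share of calls lost. At 3 d the sugar starvation list kept its direction under every alternative run on it. Its call by camera with the preset correlation and by fry was kept in each fit without a library, and its call with an estimated correlation ended in 3 of these 7 fits (largest adjusted p = 0.0623). At the same duration SEN5 and DIN10 passed in every alternative run on them but the minimum log2 fold change of 1, which their values of 0.46 and 0.62 do not reach. Another scaling (DESeq2 size factors) shifted the median of all genes by -0.003 at 1 d and -0.0012 at 3 d, and of the list means it flipped that of membrane lipids at 1 d. Depth limited the comparisons: thinned to 3695511 counts per library, 84 genes were called at 3 d and 99 between the controls.

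Genes changed at 1 d numbered 0, but 28 without the low-count filter, 1 with limma-voom, 16 with only the 2 groups in the fit and 0 to 5 when a library was left out. They were 2 with the 16 columns and 2 with the duplicated library as moc_1d. At 3 d the count of 102 became 196 without the filter, 3 with an absolute log2 fold change of at least 1, 66 with the 16 columns and 43 to 124 without a library. DESeq2 called 128, of which 88 were shared. Genes whose response differed (8) numbered 47 without the filter, 16 with DESeq2, 2 with limma-voom and 2 with an absolute log2 fold change of at least 1. They were 0 with the 16 columns, 4 with the library as moc_1d and 1 to 23 without a library. The count of genes that differ between the controls of 3 d and 1 d (155) was 283 without the filter, 27 with an absolute log2 fold change of at least 1, 67 to 134 without a library, 5 with the 16 columns and 19 with the library as moc_1d, against 176 with it as moc_3d. Without the filter more genes are tested. The cause of the differences was not tested.

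Gene lists called at 1 d (2) numbered 0 with an estimated correlation, 0 by fry, 5 with the 16 columns, 4 with the library as moc_1d and 2 to 5 without a library. At 3 d (5) there was 1 with an estimated correlation, 1 by fry and 2 to 7 without a library. For the difference of responses (2) there were 0 with an estimated correlation, 0 by fry, 1 with the 16 columns, 1 with the library as moc_1d and 1 to 6 without a library. Between the controls (7) there were 0 with an estimated correlation, 0 by fry, 3 with the library as moc_1d and 4 to 10 without a library. The cause was not tested beyond the estimated correlation, which allows for members that vary together.

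Samples that share a replicate number did not deviate together: the correlations of same-numbered ethanol and control libraries ran from -0.113 to 0.089, and not every library correlated best with its own number. With a replicate block there were 8 genes at 1 d, 73 at 3 d (62 shared with the 102), 10 for the difference of responses and 2 shared by the durations. With the block 4 lists were called at 1 d, 3 at 3 d and 0 for the difference. The block could not be fitted to the control comparison, because blocks are numbered within a duration.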

Other observations

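The comparison of EtOH_3d with EtOH_1d, the sulfur list and the genes named in this part were chosen after the data were seen, as was the test of the sulfur list against a change in the control libraries alone. The test of that list against a bound was written down before its result.

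Seedlings of 3 d also differed from those of 1 d within the ethanol groups, which share no library with the controls. There 185 genes were called by edgeR, 117 higher and 68 lower at 3 d. Of these, 43 were also called between the controls, all in the same direction, where independent lists would share 0.616 higher and 0.214 lower genes. Of the 155 genes called between the controls, 139 had the same sign in the ethanol groups. JAZ7 rose by 2.67 ± 0.30 (SE) in the ethanol groups and 2.45 in the controls, JAZ9 by 0.90 ± 0.17 and 0.82, and WRKY22, a defence transcription factor, by 0.95 ± 0.18 and 0.85. EXPA1, an expansin, fell by 0.49 and 0.50, and GLK2, a regulator of chloroplast genes, fell by 0.40 and 0.41. BT2 rose by 0.77 ± 0.07 and 0.45, and BT5, of the same BTB/TAZ family, by 0.59 ± 0.08 and 0.61. The sugar starvation list had a mean of 0.24 in the ethanol groups (SE 0.055) and 0.11 in the controls (SE 0.055). The auxin and growth list had a mean of -0.22 (SE 0.076) and -0.16 (SE 0.07). By camera with an estimated correlation, p = 0.00375 and 0.402 for sugar starvation and p = 0.00212 and 0.0228 for auxin and growth, in this order and not adjusted over the lists.

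Some single genes among the 102 called at 3 d have not been described above. They were not tested as groups, and their values do not show that a function changed. The nitrate reductases NIA1 (0.38 ± 0.08) and NIA2 (0.29 ± 0.06) were higher with ethanol. RFNR2 (-0.43 ± 0.09), the root-type ferredoxin FD3 (-0.33 ± 0.07), the glutamine synthetase GSR2 (-0.26 ± 0.06) and the transaldolase TRA2 (-0.37 ± 0.08) were lower. The autophagy gene ATG8E (0.40 ± 0.08), the SnRK1 subunit KING1 (0.33 ± 0.08) and the dormancy-associated DYL1 (0.42 ± 0.07) were higher. The ABA-degrading CYP707A3 had the largest fall (-1.39 ± 0.29), from 8.38 to 3.04 CPM.

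Single genes linked to sulfur limitation were called higher in the 3 d controls than in the 1 d controls, with LSU3 at 1.39, LSU1 at 1.07 and the reductase genes APR1 at 0.55, APR2 at 0.39 and APR3 at 0.43. A list of 14 such genes was put together because of them, so its mean of 0.63 (SE 0.08) between these controls reflects that choice and tests nothing. The list was also higher in EtOH_3d than in EtOH_1d, libraries not used to pick it, with a mean of 0.284 (SE 0.07). This argues against a change in the control libraries alone, with p = 0.00598 by fry and p = 0.0172 by camera with an estimated correlation, and every EtOH_3d library lay above every EtOH_1d library. The mean was below the bound set in advance, taken from the mean in the controls, so a change that goes with duration did not meet that bound. The bound as written made no allowance for spread, and the mean missed it by less than its spread. Since the list was higher in EtOH_3d too, it may still rise with duration in both treatments. Whether it rises less with ethanol is left open.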
